A study of Mus musculus with 30 samples.

How the data were processed

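RNA-seq and ATAC-seq libraries of fluorescence-sorted mouse RGCs were analysed from the deposited processed files. Per the labels, the retina was dissociated with papain, 5000 to 10000 sorted cells went into an RNA library made with SMART-Seq v4, and 50000 to 100000 into an ATAC library. Of the 15 labelled RNA samples, 13 had values in the tables used here. The planned tests assumed 15. For RNA the submitters' processing notes name STAR, Picard, HTSeq and edgeR with build mm10. For ATAC they name FastQC, Trim Galore, Bowtie2, SAMtools, Picard, MACS2, bedtools, ChIPseeker, featureCounts, Subread and DESeq2 with builds GRCm38 and mm10. Their versions are not given in the sources used here. The RNA kit is not stranded, so overlapping genes on opposite strands cannot be told apart.

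The deposited tables hold whole-number counts per gene for RNA and per peak for ATAC, and these counts were the input to all tests of genes and peaks. The authors' normalized RNA values and batch-adjusted ATAC values are on a log2 scale, and so are the fold changes in their comparison tables. The deposited chromVAR table holds a z-score per motif and library, and the deposited footprint tables hold a footprint score per site and day with libraries pooled. Per the file headers, the share of reads in peaks, the duplicate rate and the GC content are given as a fraction. Each adjusted p-value in the comparison tables is the authors'. The deposited peak calls of single libraries give a ratio, the fold enrichment of MACS2, for each peak. The authors' covariate tables also give a batch for each ATAC library and 7 principal components of sequencing metrics for each RNA library. The chromVAR variability per motif was not used here.

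Genes and peaks were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, two-sided, with TMM normalization, filterByExpr and day as the only term. All libraries of an assay entered 1 fit, and values of adjusted p were by Benjamini and Hochberg with a threshold of 0.05. The standard error of a log2 fold change was the fold change divided by the square root of F. A prior count of 2 entered log2 CPM values only, not the fitted fold changes. A gene with no counts in any library of a group was given a floor of 3 counts per library, and such floors and intervals cover counting error only. Motif scores were tested with limma 3.58.1 over 1312 motifs. The deposited normalized RNA values were at their floor in 92 gene and library pairs with no counts. The main tests, the gene lists, the motif families, the rule for named genes and the following alternatives were chosen before the data were examined: DESeq2 1.42.0 (Wald test, and its size factors in edgeR), no filter or a mean count of at least 20, only the groups compared in the fit, replicate number as a term, a fold change of at least 2, the share of reads in peaks as a term, library size only, exact permutation tests and centring of motif scores, and leaving out each library in turn. Chosen after seeing the data were a batch term, single batches, removal of the trend with peak strength by a lowess curve per library (span 0.3), tests on the deposited normalized or batch-adjusted values, and the first pair of sequencing components as terms. The RNA, gene list and motif comparisons of day 3 against day 1 were not among the planned main tests, while that of ATAC peaks was.

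There were 22 gene lists and 17 motif families. The lists covered RGC identity, RGC subtype, axon injury, the integrated stress response, endoplasmic reticulum chaperones, apoptosis, DLK and JNK signalling, interferon, neurotrophic receptors, excitability and synapse, axon transport and cytoskeleton, cholesterol synthesis, oxidative phosphorylation, immediate early genes, and markers of rods, cones, bipolar cells, amacrine and horizontal cells, Mueller glia and astrocytes, microglia and macrophages, vascular cells and oligodendrocytes. Each was tested against the other genes with camera at a preset correlation of 0.01 and at an estimated correlation. It was also tested with fry, which asks whether the genes of a list moved one way on balance and does not compare them with other genes. All tests against day 0 were adjusted over lists and days. Those of day 3 against day 1 were adjusted over the lists alone. The marker lists share genes with RGCs, among them Isl1, Pax6, Clu, Vim, Aldoc and Cd68. Genes were named by a rule. For each day these were the 10 largest rises and 10 largest falls among genes that passed, with a mean of at least 5 CPM (counts scaled to library size) and no overlap between the libraries of the day and of day 0, which chance gives in 10% of cases for 3 libraries against 3. To these came up to 4 members per list with the smallest adjusted p and 9 genes chosen in advance. Peaks were the 5 largest rises and falls with a mean count of at least 20 and no overlap. For each gene chosen in advance, the annotated peak with the smallest p was added. Motifs were the 10 largest each way and the family members with the smallest adjusted p. Some genes and motifs that the rule names, and 1 motif family, are not reported here.

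Promoter accessibility was taken from the peak with the highest mean count among those that the deposited annotation places at a gene's promoter, and set against RNA across genes with 100000 permutations. Groups of calls were compared with Fisher's exact test. Sums of markers were compared with exact permutation tests. Other splits of the libraries were tested on 20000 peaks drawn at random, with up to 100 splits. Tables and figures also used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

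The tests of genes and peaks were checked on simulated data made from the deposited counts with 200 changed genes or peaks. Of genes simulated at a fold of 1.5, edgeR recovered 37.3%, 17.9%, 28.4% and 17.9% for days 1 to 4, so that most simulated changes of that size were missed. At a fold of 2 it recovered 70.1%, 61.2%, 73.1% and 56.7%, and at a fold of 4 it recovered 77.3%, 86.4%, 92.4% and 86.4%. For ATAC with a batch term these were 13.4% and 29.9% at a fold of 1.5 on days 1 and 3, 68.7% and 86.6% at a fold of 2, and 98.5% and 100% at a fold of 4. Of the calls, 0% to 4.44% were false for RNA and 7.69% and 9.43% for ATAC. A first criterion, over 80% recovered at a fold of 4, was not met for RNA on day 1, and it was replaced after that was seen by limits on the estimated fold and on false calls. For motifs, scores were drawn as independent normal values with an SD of 5, not from the deposited scores. With a shift of 15, limma recovered 97% of 200 simulated shifts, with 9 false calls. Correlation between motifs and shifts of whole libraries were not simulated, so these rates may not carry over to the deposited scores.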

Results

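Retinal ganglion cells (RGCs) are the neurons whose axons form the optic nerve. Crushing that nerve injures all of these axons, and the question of the study was how gene expression and open chromatin in RGCs change in the days that follow. RGCs of mice were freed from the retina with papain and sorted by fluorescence. RNA-seq covered an uninjured group, called day 0 here, and days 1, 2, 3 and 4 after crush. ATAC-seq, in which a transposase cuts open chromatin, covered days 0, 1 and 3. The strain label is C57BL/6, except for day 0 RNA replicates 2 and 3, labelled C57BL/7 and C57BL/8, and whether those name other strains was not settled. The labels list 30 samples, 15 of RNA (3 per day) and 15 of ATAC (6, 3 and 6 on days 0, 1 and 3). Of the RNA samples 13 were analysed, with n = 3, 3, 2, 3 and 2 on days 0 to 4, and day 2 replicate 3 and day 4 replicate 1 were not analysed here. RNA libraries held 19024286 to 27561352 counts in genes, and their most abundant gene, Snap25 or Malat1, took 1.53% to 3.65% of them. ATAC libraries held 20006724 to 72579102 counts in 151630 peaks. The labels do not say that replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

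On day 1, several genes known from stress, injury and cell death had risen strongly, while the falls were small. Atf3, a stress-induced transcription factor, rose 14.3-fold (log2 3.84 ± 0.16, SE; edgeR adjusted p = 1.13e-10). Sox11, a transcription factor of developing neurons, rose 7.49-fold, Ddit3 (the pro-apoptotic factor CHOP) 5.79-fold, and Jun, a part of the AP-1 factor, 5.37-fold. The pro-apoptotic gene Hrk rose 19.9-fold (log2 4.32 ± 0.16, adjusted p = 3.2e-11 with edgeR), Dusp16, which encodes a phosphatase of the kinase JNK, 17.6-fold, Tmc1, which encodes a mechanosensory channel subunit, 20.2-fold, and the RNA-binding protein gene Arid5a 15.3-fold. The largest falls were those of Slc25a35, a mitochondrial carrier gene (log2 -1.42 ± 0.29), the histamine receptor gene Hrh3 (-1.35 ± 0.22), Samd1 (-1.35), Ell3 (-1.18), the tubulin gene Tubb4b (-1.13 ± 0.13), Ndp, which encodes the ligand norrin (-1.12), and the cyclin gene Ccne1 (-1.11).

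With edgeR, 1563 of 13737 genes tested changed on day 1, 815 higher and 748 lower, and 3536 had an unadjusted p under 0.05. The rises were larger than the falls, with 341 genes at least 2-fold higher and 25 at least 2-fold lower. The count was 815 when only the libraries of days 0 and 1 entered the fit, and 1024 without day 1 replicate 1. Several of the largest rises depended in size on 1 uninjured library. With day 0 replicate 3 left out, the rise of the transcription factor gene Creb5 went from 74.2-fold to 338-fold, that of the metalloelastase gene Mmp12 from 36.2-fold to 120-fold, and that of the receptor gene Tnfrsf12a from 11.1-fold to 24.1-fold. Leaving out day 0 replicate 1, the rise of the pseudokinase gene Trib3 went from 16.6-fold to 36.5-fold, and without day 0 replicate 2 Creb5 was at 48.3-fold. Colec10, a collectin gene, had no counts on day 0 and was at least 4.39-fold higher on day 1, against a floor of 3 counts per library. The exchange factor gene Rasgrp2 (log2 -1.26), the adrenergic receptor gene Adra2a (-1.10) and Pinx1, of telomere control (-1.08), lost their calls with edgeR when single libraries were left out. For Rasgrp2 this held without day 0 replicate 1 or 2 or day 1 replicate 1, 2 or 3 (adjusted p = 0.0785 to 0.126), for Adra2a without day 0 replicate 3 or day 1 replicate 1 or 2 (0.0765 to 0.0879), and for Pinx1 without day 0 replicate 2 or 3 or day 1 replicate 1 or 3 (0.0643 to 0.110).

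On day 2, Atf3, Hrk, Sox11 and Ddit3 stood at larger folds than on day 1, and the largest falls were several-fold. Atf3 was up 63.6-fold (log2 5.99 ± 0.17, edgeR adjusted p = 5.01e-13), Hrk 64.2-fold, Tmc1 123-fold and Arid5a 55.1-fold. Sox11 was up 19.8-fold (adjusted p = 1.5e-14 with edgeR) and Ddit3 13.2-fold. Among the largest falls were the neuropeptide gene Cck (log2 -3.08 ± 0.30), the calcium buffer gene Calb1 (-3.05 ± 0.16), Hrh3 (-2.91), the tubulin-binding protein gene Tppp3 (-2.74 ± 0.11), Tubb4b (-2.57) and the nicotinic receptor gene Chrna6 (-2.50 ± 0.11). The sodium channel subunit gene Scn4b (-4.33), Rasgrp2 (-3.24) and the adrenergic receptor gene Adra2c (-2.51) also fell. Day 2 had 2 libraries, and edgeR called 4020 genes, 2034 higher and 1986 lower, or 2427 without day 2 replicate 2 and 2612 without day 2 replicate 1. At an unadjusted p under 0.05 there were 5446 genes. Without day 0 replicate 3, the rises of Mmp12 (154-fold), Sprr1a (109-fold), Creb5 (103-fold) and Tnfrsf12a (37.2-fold) were 509-fold, 1150-fold, 468-fold and 81.2-fold, and that of Crabp2 (34.3-fold) was 22.4-fold. Creb5 was at 66.9-fold and Crabp2 at 53.9-fold without day 0 replicate 2. Colec10 was at least 43.5-fold higher than day 0.

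On day 3, Atf3 was 141-fold above day 0 (log2 7.14 ± 0.18, edgeR adjusted p = 4.88e-14), and the peptidase gene Ecel1 (175-fold) and Sema3c, which encodes a secreted guidance protein (149-fold), had joined the largest rises. Hrk was up 77.7-fold (77.65), Sox11 21.6-fold and Ddit3 11.1-fold. Markers of RGCs were lower: Pou4f2, a transcription factor of RGC development, by 2.06 on the log2 scale (± 0.10), Pou4f1 by 1.39 and Rbpms, an RNA-binding protein gene used as an RGC marker, by 1.18. Of single genes, Rasgrp2, a nucleotide exchange factor gene (log2 -5.01 ± 0.48), and the gene 1500009C09Rik (-4.62 ± 0.25) had among the largest falls. Among the 10 largest falls 7 were interferon-induced genes (Ifi44, Iigp1, Gbp3, Ifit1, Oasl2, Ifit3 and Gbp6), whose day 0 level came from 1 library. With edgeR, 5564 genes changed, 2803 higher and 2761 lower, and 6537 had an unadjusted p under 0.05. At a fold change of at least 2 there were 2136, 976 higher and 1160 lower. Sprr1a rose 414-fold, Mmp12 241-fold and Creb5 61.1-fold, and without day 0 replicate 3 these were 4390-fold, 803-fold and 279-fold. Cox6a2 rose 83.7-fold and Snx33 61.6-fold, which became 212-fold and 292-fold without day 0 replicate 1 and 54.4-fold and 40.1-fold without replicate 2, where Creb5 stood at 39.9-fold. Colec10 was at least 270-fold higher than day 0.

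On day 4, the pattern of day 3 held for the injury genes, and Chrna6, Calb1 and Pou4f2 stood at their lowest of the days measured. Ecel1 was up 257.5-fold, Atf3 161-fold (log2 7.33 ± 0.18, edgeR adjusted p = 5.18e-14), Sema3c 143-fold and Hrk 102-fold. Sox11 reached 31.9-fold. Chrna6 was down by 5.06 on the log2 scale (± 0.13, adjusted p = 5.93e-14 with edgeR), Hapln1, which encodes a link protein of the extracellular matrix, by 5.67, the hormone receptor gene Trhr by 5.31, and Calb1 by 4.83. Sptssb, of sphingolipid synthesis (log2 -4.845), the dynein gene Dnah6 (-4.73) and 1500009C09Rik (-4.71) fell as well. Day 4 had 2 libraries, and edgeR called 5337 genes, 2721 higher and 2616 lower, with 6373 at an unadjusted p under 0.05. Without day 0 replicate 3, the rises of Sprr1a (256-fold) and Mmp12 (245-fold) were 2720-fold and 819-fold. The rise of the integrin gene Itga5 (56.1-fold) was 101-fold and that of Snx33 (56.3-fold) 36.7-fold without day 0 replicate 2, and Snx33 was at 267-fold without day 0 replicate 1. The falls of Scn4b (log2 -6.02) and the peptidase gene Mme (-4.94) were -5.38 and -6.58 without day 4 replicate 2 and -6.96 and -4.26 without day 4 replicate 3. Xist, the RNA of the inactive X chromosome, was called 60.6-fold higher, but its level differed between libraries of the same day. Its fold was 7040 without day 0 replicate 1, without replicate 2 40.2 and without replicate 3 40.3. Colec10 was at least 332-fold higher than day 0.

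**Figure D1:**
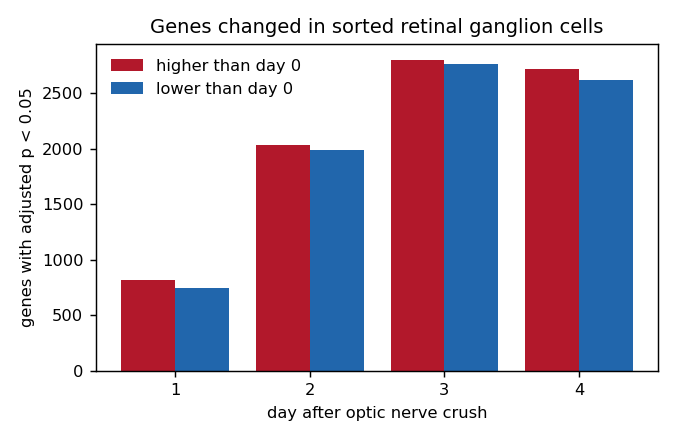
Number of genes higher (red) and lower (blue) than on day 0 for days 1 to 4 after crush, by edgeR at an adjusted p under 0.05. The bars grow from 815 and 748 genes on day 1 to 2803 and 2761 on day 3, and stand at 2721 and 2616 on day 4.

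Day 3 was also set directly against day 1, which was not planned for RNA. The 2 days differed by 4605 genes with edgeR, 2206 higher and 2399 lower on day 3, and 5812 had an unadjusted p under 0.05. Members of the integrated stress response, the program driven by ATF4 that adjusts amino acid supply and protein synthesis, were higher again (32 of 36 rose, 0 fell; median log2 1.32; camera adjusted p = 5.06e-24, and adjusted p = 0.0374 with an estimated correlation). Axon injury genes were higher in 17 of 25 cases and lower in 3 (median log2 1.26; camera adjusted p = 2.67e-10, and adjusted p = 0.0137 with an estimated correlation). Genes of excitability and synapses were lower in 28 of 41 cases (median log2 -0.85; camera adjusted p = 4.89e-13, and adjusted p = 0.0374 with an estimated correlation). Over all 4 days in 1 test, 6465 genes changed, and 7442 had an unadjusted p under 0.05.

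**Figure D2:**
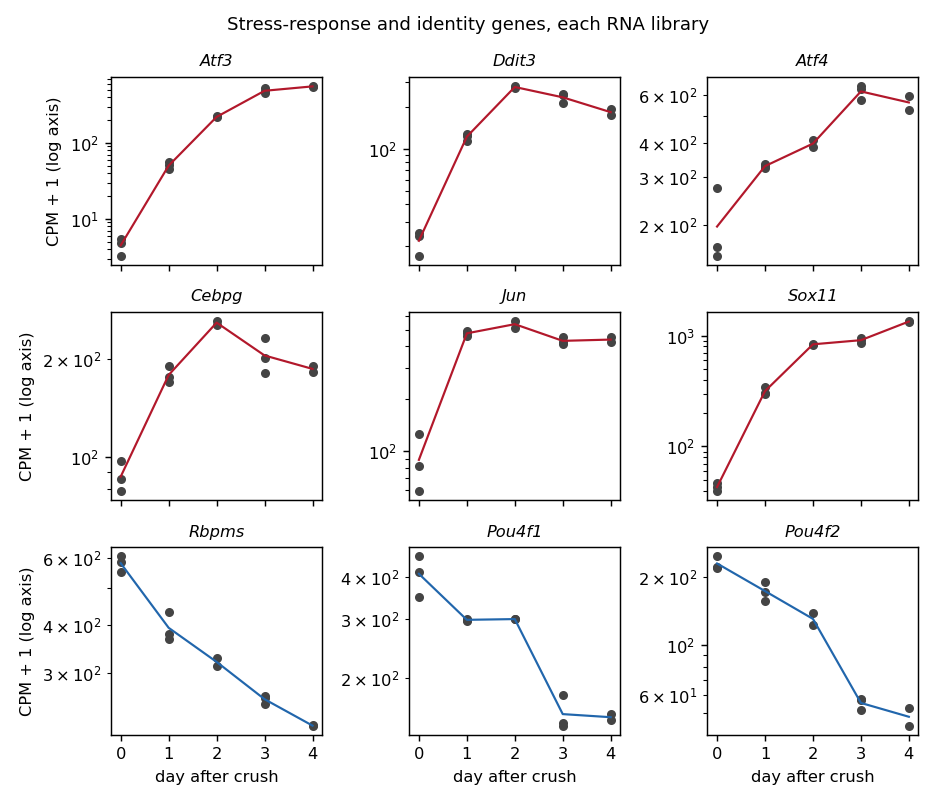
CPM (counts scaled to library size) plus 1, on a log axis, of Atf3, Ddit3, Atf4, Cebpg, Jun, Sox11, Rbpms, Pou4f1 and Pou4f2 in each of the 13 RNA libraries against the day after crush, with a line through the day means. Atf3 and Sox11 climb at each day shown, to 161-fold and 31.9-fold by day 4, while Pou4f2 ends lower by 2.27 on the log2 scale.

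The 9 genes chosen in advance moved in 2 directions. Atf4 itself, the transcription factor of the integrated stress response, rose 1.67-fold on day 1 (edgeR adjusted p = 0.00424), 2.02-fold on day 2, 3.13-fold on day 3 and 2.85-fold on day 4. Its partner gene Cebpg rose 2.06-fold, 2.98-fold, 2.36-fold and 2.15-fold. Ddit3 peaked at 13.2-fold on day 2 and was at 8.70-fold on day 4, and Jun stood between 4.86-fold and 6.07-fold from day 1 on. Rbpms fell on every day (log2 -0.56, -0.86, -1.18 and -1.41), as did Pou4f1 (-0.46, -0.45, -1.39 and -1.42). Pou4f2 fell by 0.82, 2.06 and 2.27 on days 2, 3 and 4. Its day 1 value was -0.41 (adjusted p = 0.015 with edgeR), which without day 1 replicate 3 was -0.34 (adjusted p = 0.0686).

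Genes of RGC identity were lower as a group on each day. Of 20 tested, 11, 15, 15 and 16 fell on days 1, 2, 3 and 4 and 0, 0, 1 and 2 rose, and adjusted over the list alone the falls were 11, 16, 15 and 16. The median log2 change was -0.34, -0.82, -1.12 and -1.26. Their summed CPM was 14940 on day 0 and 12270, 10350, 10620 and 9321 on days 1 to 4. Day 3 set directly against day 1 had 13 lower and 2 higher (camera adjusted p = 3.09e-06), a call lost at adjusted p = 0.0687 with an estimated correlation. The list stood below other genes by camera on each day (adjusted p = 4.22e-08, 4.3e-10, 2.15e-09 and 7.41e-10), and with adjusted p = 0.0405, 0.0298, 0.031 and 0.0302 with an estimated correlation. Chrna6 fell by 0.83, 2.50, 4.17 and 5.06, the neurofilament genes Nefh and Nefl by 1.49 and 1.08 on day 2, and Rbpms2 by 1.90 on day 3 and 2.34 on day 4. Without day 1 replicate 1, 7 members fell on day 1, with adjusted p = 0.0634 with an estimated correlation. Markers of RGC subtypes were mixed: 3, 9, 9 and 11 of 16 fell and 2, 1, 2 and 2 rose (adjusted over the list alone, 6, 9, 10 and 11 fell). Jam2, a marker of a direction-selective type, fell by 0.65, 1.44, 2.71 and 2.67, Mmp17 by 1.41, 2.48 and 2.28 on days 2 to 4, whereas the peptide gene Cartpt rose 1.97-fold on day 1 and Penk, the enkephalin precursor gene, 2.26-fold on day 4. By camera the subtype list was lower on days 1 to 4 (adjusted p = 0.00746, 0.000489, 0.00032 and 0.000467), with adjusted p = 0.0537, 0.028, 0.028 and 0.028 with an estimated correlation, so the day 1 call did not hold there.

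Axon injury genes rose in 15, 19, 22 and 23 of 25 cases on days 1 to 4 and fell in 1, 2, 2 and 1 (adjusted over the list alone, the same rises and 1, 2, 2 and 2 falls), with a median log2 change of 1.30, 1.95, 2.28 and 2.49. Besides Atf3 and Sox11, Stmn4, of the stathmin family of tubulin regulators, rose 5.70-fold, 6.70-fold, 6.43-fold and 5.52-fold, Gadd45a 16.2-fold on day 3 and the transcription factor gene Klf6 4.25-fold on day 4. The integrated stress response list rose in 29, 35, 35 and 35 of 36 cases and fell in 0, 0, 0 and 1 (adjusted over the list alone, 31, 35, 36 and 35 rose and 1, 0, 0 and 1 fell), with a median log2 change of 1.09, 2.10, 2.39 and 2.08. Shmt2, a mitochondrial enzyme of serine metabolism, rose 2.55-fold, 6.18-fold (6.175), 9.58-fold and 7.91-fold, the stress gene Sesn2 4.16-fold on day 1 and 10.9-fold on day 4, and the tRNA synthetase genes Sars, Eprs and Wars 3.28-fold (day 2), 3.34-fold (day 3) and 2.80-fold (day 3). Both lists were above other genes by camera, with adjusted p of 1.91e-16 to 2.46e-13 for axon injury and 2.32e-29 to 2.4e-22 for the stress response. With an estimated correlation these were adjusted p = 0.0064 to 0.00701 and 0.028 to 0.0405, and the values of the stress response on days 1 and 4 were 0.057 each without day 0 replicate 3.

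Cell death genes rose in 6, 10, 15 and 14 of 27 cases and fell in 1, 1, 0 and 2 (adjusted over the list alone, 9, 10, 15 and 14 rose and 3, 2, 2 and 2 fell). Bcl2l11, a pro-apoptotic gene like Hrk, rose 8.92-fold, 18.5-fold, 14.98-fold and 21.8-fold, and the cell cycle inhibitor gene Cdkn1a 4.15-fold, 15.9-fold, 37.8-fold and 39.7-fold. By camera the list was higher on each day (adjusted p = 0.0148, 0.0115, 0.000467 and 0.000887), with adjusted p = 0.0619, 0.0607, 0.028 and 0.028 with an estimated correlation, so that the calls of days 1 and 2 did not hold there. Genes of DLK and JNK signalling, the kinase pathway that carries the axon injury signal, went both ways. Of 20, 3, 6, 8 and 9 rose and 3, 6, 5 and 5 fell (adjusted over the list alone, 4, 7, 8 and 9 and 4, 6, 6 and 6), and camera made no call (adjusted p = 0.154, 0.288, 0.259 and 0.409, the last with a median of -0.08 but the direction up). By fry, which does not compare with other genes, the list was higher on each day (adjusted p = 4e-05, 4e-05, 1.36e-05 and 3.06e-05). Dusp16 and Jun rose, as did the kinase gene Tnik (3.45-fold on day 3 and 3.83-fold on day 4), while Mapk10, which encodes a JNK, fell (log2 -1.14 on day 3 and -1.502 on day 4). Endoplasmic reticulum chaperone genes were mixed, with 1, 6, 6 and 6 of 16 higher and 2, 4, 3 and 1 lower (adjusted over the list alone, 2, 6, 6 and 6 and 8, 4, 4 and 1). Herpud1, of the degradation of misfolded proteins, rose 2.20-fold to 3.31-fold, and the chaperone gene Hspa5 2.90-fold on day 3 and 2.92-fold on day 4, whereas Hyou1 fell by 0.785 on day 1. The list was lower on day 1 by camera (adjusted p = 0.0114, lost at adjusted p = 0.188 with an estimated correlation) and not called later (0.678, 0.367 and 0.154), where its median was at -0.18 on day 3 with the direction up. Falling members on day 1 numbered 6 without day 0 replicate 1 and 5 without day 1 replicate 1, and without day 1 replicate 2 the camera adjusted p of the list ER chaperones day 1 against day 0 was 0.0519.

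**Figure D3:**
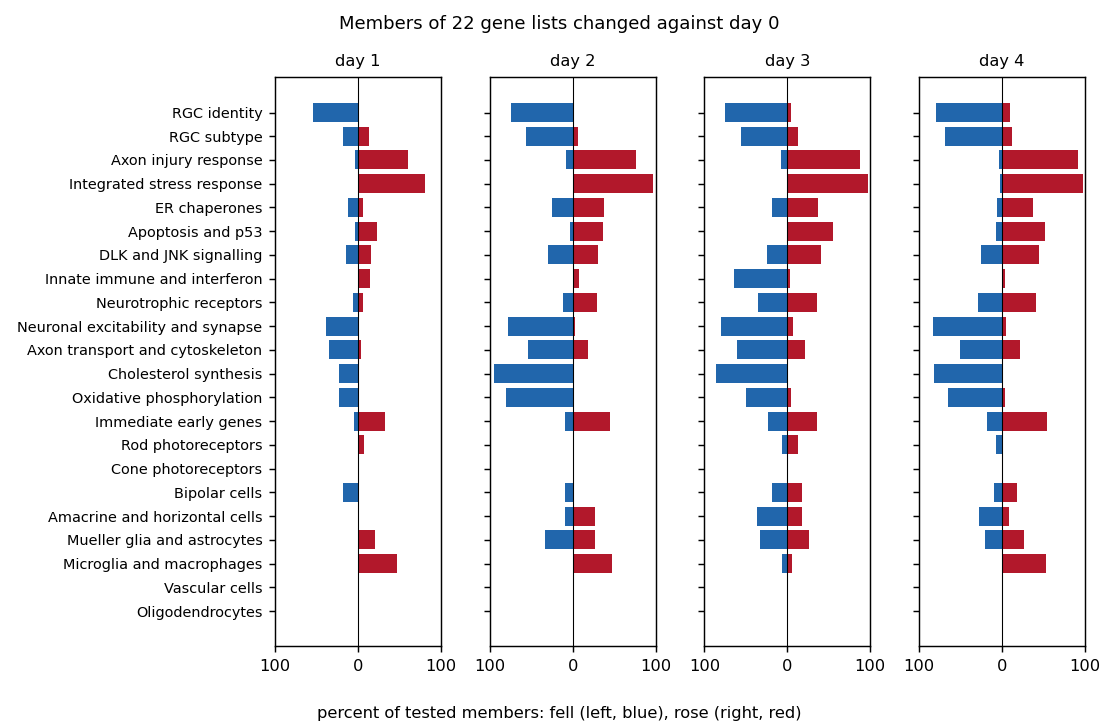
Percent of the tested members of each of 22 gene lists that fell (blue, to the left) or rose (red, to the right) against day 0 on days 1 to 4, by edgeR over all genes. Integrated stress response genes rise almost throughout (29 to 35 of 36), and genes of excitability and synapses fall (16 to 34 of 41).

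Genes of excitability and synapses fell in 16, 32, 33 and 34 of 41 cases and rose in 0, 1, 3 and 2 (adjusted over the list alone, 28, 33, 34 and 35 fell and 1, 1, 3 and 2 rose), with a median log2 change of -0.30, -0.66, -1.23 and -1.45. Pvalb, which encodes a calcium buffer, fell by 2.47, 2.86 and 3.93 on days 2, 3 and 4, the potassium channel gene Kcna2 by 0.50, 1.69 and 2.16 on days 1, 3 and 4, and the sodium channel gene Scn1a by 1.10, 1.70 and 2.12 on days 2 to 4. Camera placed this list below other genes on each day (adjusted p = 1.78e-16, 4.47e-18, 1.05e-17 and 7.16e-21), with adjusted p = 0.028 on each day with an estimated correlation. Axon transport and cytoskeleton genes fell in 10, 15, 17 and 14 of 28 cases and rose in 1, 5, 6 and 6 (adjusted over the list alone, 15, 18, 17 and 16 and 2, 5, 6 and 6). Here the tubulin genes fell, Tuba1b by 0.90, 2.32, 2.38 and 2.52 and Tubb4a by 0.63, 2.23, 2.52 and 2.41, while Stmn4 rose. The camera calls (adjusted p = 5.09e-06, 1.43e-06, 0.000963 and 0.00127) were lost at adjusted p = 0.0718, 0.0619, 0.188 and 0.192 with an estimated correlation. On day 2, 2 members rose without day 0 replicate 1, and without day 1 replicate 1, 3.

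Most cholesterol synthesis genes were lower from day 2 on. Of 22, 5, 21, 19 and 18 fell and 0 rose (adjusted over the list alone, 5, 21, 19 and 19 fell), with a median log2 change of -0.21, -1.08, -1.12 and -1.33. Insig1, which encodes a sterol-sensing regulator of the pathway, fell by 0.41, 1.44, 1.37 and 1.65, and Hmgcs1, of an early step, by 0.49, 1.37, 1.46 and 1.53. The camera adjusted p was 0.000942, 4.65e-14, 1.01e-10 and 1.09e-11. The group call held on day 2 only with an estimated correlation (adjusted p = 0.0465) and was lost on days 1, 3 and 4 (adjusted p = 0.353, 0.0718 and 0.0636). On day 1, 3 members fell without day 0 replicate 3 and camera made no call (adjusted p = 0.0568). Oxidative phosphorylation genes fell in 6, 21, 13 and 17 of 26 cases and rose in 0, 0, 1 and 1 (adjusted over the list alone, 9, 24, 14 and 21 and 0, 0, 1 and 1). Ndufa4, of the respiratory chain, fell by 0.39, 1.29, 0.62 and 0.80, and Atp5g1, an ATP synthase subunit gene, was the 1 member that rose on day 3 (1.997-fold). The camera adjusted p was 5.01e-06, 1.39e-12, 0.000699 and 5.01e-06, and it was adjusted p = 0.156, 0.0405, 0.277 and 0.156 with an estimated correlation, so that only the day 2 call held there. Without day 1 replicate 1 or day 0 replicate 3, 2 members fell on day 1.

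Receptors for neurotrophic factors moved apart. Of 17, 1, 5, 6 and 7 rose and 1, 2, 6 and 5 fell (adjusted over the list alone, 1, 5, 7 and 8 and 1, 2, 6 and 5), and camera made no call (adjusted p = 0.981, 0.444, 0.399 and 0.144), while by fry the list was higher on days 2 to 4 (adjusted p = 0.00753, 0.000553 and 6.68e-05; on day 1 0.822). Fgfr1, a fibroblast growth factor receptor gene, rose 1.53-fold, 4.27-fold, 7.935-fold and 9.73-fold, Il6st and Lifr, receptor genes for cytokines of the interleukin-6 family, 2.41-fold and 2.71-fold on day 4, and Ntrk3, a neurotrophin receptor gene, fell by 1.57 on day 3 and 1.59 on day 4. Immediate early genes, a sign of recent activity or of handling, rose in 7, 10, 8 and 12 of 22 cases and fell in 1, 2, 5 and 4 (adjusted over the list alone, 8, 12, 8 and 12 and 2, 2, 6 and 4). Egr1 rose 2.33-fold, 3.96-fold, 2.96-fold and 2.52-fold and Fosl2 3.94-fold and 4.03-fold on days 3 and 4. Camera placed them above other genes on days 1, 2 and 4 (adjusted p = 0.0363, 0.00451 and 0.0134; on day 3 0.283), which was lost at adjusted p = 0.233, 0.115 and 0.182 with an estimated correlation. Without day 1 replicate 1, 4 rose on day 1, and the day 1 call by camera was lost without day 0 replicate 2 (adjusted p = 0.0639) or day 1 replicate 3 (0.0896 for the list Immediate early genes day 1 against day 0).

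Interferon-induced genes followed single libraries. Uninjured replicate 3 held 5030 CPM (counts scaled to library size) summed over the list, against 598.6 and 697.2 in replicates 1 and 2, and the libraries of day 1 held 3744 to 5856, of day 2 2490 and 6227, of day 3 525.0 to 581.7 and of day 4 1645 and 1812. With all libraries, 4, 2, 1 and 1 of 28 rose and 0, 0, 18 and 0 fell (adjusted over the list alone, 4, 1, 1 and 1 and 0, 0, 19 and 0). Without day 0 replicate 3, 23, 21, 2 and 14 rose and 0, 0, 4 and 0 fell, and the median log2 change on day 3 went from -1.93 to -0.23. The camera adjusted p was 4.3e-10, 5e-04, 0.111 and 0.452 with all libraries and adjusted p = 0.239, 0.523, 0.85 and 0.926 with an estimated correlation. Without day 0 replicate 3 it was 6.21e-19, 4.7e-09, 0.749 and 0.00342, and adjusted p = 0.0685, 0.227, 0.933 and 0.605 with an estimated correlation, where no call held in either case. On day 4 the median with all libraries was -0.33 while the direction of the test was up. Of the large falls on day 3, Ifi44 went from log2 -6.54 to -3.41 without that library, Gbp3 from -5.81 to -2.33, Ifit3 from -4.52 to -1.98, Oasl2 from -4.68 to -1.20 and Gbp6 from -4.43 to -1.34, while Iigp1 (from -5.93 to -2.30, adjusted p = 0.0695 with edgeR) and Ifit1 (from -4.72 to -1.27, adjusted p = 0.0649 with edgeR) lost their calls. Without day 1 replicate 1, 0 members rose on day 1, and without day 0 replicate 1 21 fell on day 3 (camera adjusted p = 0.0257, and adjusted p = 0.697 with an estimated correlation).

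Markers of other retinal cell types were present in the sorted cells. In single libraries their sums reached 1349 CPM for rods, 1352 for amacrine and horizontal cells, 1739 for microglia and macrophages and 2214 for Mueller glia and astrocytes, against 9069 to 16060 for RGC identity and 689.9 to 1463 for RGC subtypes, and the lists differ in length. Summed microglia and macrophage markers were at 231 ± 73.4 CPM (SD, n = 3) on day 0, 799 ± 817 (n = 3) on day 1, 564 ± 40.4 (n = 2) on day 2, 269.8 ± 30.6 (n = 3) on day 3 and 598 ± 125 (n = 2) on day 4, and day 1 replicate 1 alone held 1739. The exact two-sided permutation test of the sums could call no day, since it cannot give less than p = 0.1 with these sample sizes. By that test days 2 and 4 stood at this smallest value of 0.1, and days 1 and 3 at 0.2 and 0.4. Gene by gene, 8, 8, 1 and 9 of 17 rose and 0, 0, 1 and 0 fell (adjusted over the list alone, 15, 13, 1 and 9 and 0), and without day 1 replicate 1 1, 12, 1 and 11 rose and 0, 0, 6 and 0 fell. On day 2, 5 rose without day 0 replicate 3. Camera gave an adjusted p of 3.95e-05, 5e-04, 0.68 and 0.00384, lost at adjusted p = 0.44, 0.523, 0.947 and 0.597 with an estimated correlation. Cd68, a lysosomal gene that neurons express too, rose 6.37-fold, 18.6-fold and 16.03-fold on days 2, 3 and 4, and C1qa, a complement gene, 3.89-fold on day 4. Rod markers summed to 704 ± 551 CPM on day 0, where replicate 1 held 1336, and to 1162 ± 171, 417.9 ± 88.4, 930.0 ± 88.9 and 619.4 ± 329 on days 1 to 4. Of 15 rod genes, 1, 0, 2 and 0 rose and 0, 0, 1 and 1 fell (adjusted over the list alone, 1, 0, 0 and 0 and 0, 0, 0 and 1), while 11, 2, 12 and 3 rose without day 0 replicate 1 and 5 fell on day 2 without day 0 replicate 3. The camera call on day 1 (adjusted p = 5.09e-06) was lost at adjusted p = 0.357 with an estimated correlation. Of cone (8 genes), vascular (7) and oligodendrocyte (3) markers, 0 changed on any day by edgeR.

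Markers of bipolar, amacrine and horizontal cells and of glia were partly genes that RGCs express as well. Of 11 bipolar genes, 0, 0, 2 and 2 rose and 2, 1, 2 and 1 fell, with Isl1, a transcription factor gene of bipolar cells and RGCs, down by 0.55, 0.82, 1.27 and 1.49. Of 11 amacrine and horizontal cell genes, 0, 3, 2 and 1 rose and 0, 1, 4 and 3 fell, with Pax6, active in RGCs too, down by 0.50, 1.63 and 1.72 on days 2 to 4. The summed CPM of this list was 1089 on day 0 and 1076, 1256, 792.3 and 793.3 on days 1 to 4. Of 15 Mueller glia and astrocyte genes, 3, 4, 4 and 4 rose and 0, 5, 5 and 3 fell, and their summed CPM was 1871 on day 0 and 2067, 1216, 1055 and 1280 on days 1 to 4. Among these Clu, a secreted chaperone gene, rose 1.73-fold, 1.97-fold, 2.88-fold and 4.33-fold and the adhesion receptor gene Cd44 11.25-fold on day 3 and 25.2-fold on day 4, while Aldoc, of glycolysis, fell by 1.52, 2.24 and 3.19 on days 2 to 4. Camera made no call for these 3 lists with all libraries on any day. The authors' deposited table of RNA comparisons lists 723 changed genes for day 1 and 2709 for day 3, and of these 710 and 2249 were also called here, 710 and 2226 in the same direction.

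Between day 0 and day 3, chromatin opened at more sites than it closed. With day as the only term, edgeR called 14466 of 151630 peaks, 10857 more and 3609 less open, and 35567 had an unadjusted p under 0.05. Gained peaks lay away from promoters: 36.1% were distal, 43.6% in introns and 13.4% at promoters, against 25.4%, 38.3% and 26% of all peaks. Weak peaks also tended to gain and strong peaks to lose (Pearson r across peaks, which are not independent, -0.165 with day alone). Where gained peaks lay with that trend removed was not tested. The promoter peak of Atf3 (mm10, chromosome 1, 191216075 to 191217292) went from 2.65 ± 0.603 to 5.42 ± 1.30 CPM (SD, n = 6 and 6; log2 1.02 ± 0.19, SE; edgeR adjusted p = 0.00337; batch 1 0.93, batch 2 1.03). The largest gains were a distal peak nearest to Gm47362 (chromosome 10, 85739440 to 85740079; log2 3.00 ± 0.28; edgeR adjusted p = 5.44e-05; batch 1 3.10, batch 2 2.85), a distal peak nearest to Gm7729 (chromosome 18, 27454530 to 27455333; 2.91) and one in an intron of Gm4894 (chromosome 9, 49270793 to 49271407; 2.82). Gm22448 (2.89) and Gm23959 (2.86) were the nearest genes of the other 2. The largest losses were a peak in an intron of Rnaset2b (chromosome 17, 7005603 to 7005978; log2 -1.49 ± 0.35; batch 1 -0.75, batch 2 -2.56), distal peaks nearest to Pja1 (chromosome X, 99495117 to 99495849; -1.37) and Btg1-ps2 (-1.35), and the promoter peaks of the photoreceptor guanylate cyclase gene Gucy2f (chromosome X, 142196618 to 142197167; -1.21; batch 1 -0.82 with adjusted p = 0.0725, batch 2 -1.63) and of A930006I01Rik (chromosome 2, 103371720 to 103373580; -1.18).

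Of the other genes chosen beforehand, a peak in an intron of Rbpms (chromosome 8, 33792588 to 33793139) opened on day 3 (log2 0.83 ± 0.17, edgeR adjusted p = 0.00526), by 0.99 in batch 2 and by 0.57 in batch 1 (adjusted p = 0.298), although the RNA of Rbpms fell. For each gene only the peak with the smallest p is given, and how the other peaks of Rbpms moved was not examined. A distal peak of Sox11 (chromosome 12, 27467959 to 27468502) had a log2 change of 1.12 (adjusted p = 0.0344), and the call was lost on leaving out any of day 0 replicates 1, 2 and 3 (adjusted p = 0.0692, 0.0815 and 0.0708 for peak 12 27467959 near Sox11 day 3 against day 0) and day 3 replicates 4, 5 and 6 (0.0701, 0.0703 and 0.0635). With the batch term described below it passed on day 3 (log2 1.06, adjusted p = 0.000403; batch 1 1.14, batch 2 0.88) and on day 1 (1.35, adjusted p = 0.00867), where the value with day alone was 0.85 (adjusted p = 0.319). No peak of Atf4, Cebpg, Pou4f1 or Pou4f2 passed with day as the only term. With the batch term a promoter peak of Cebpg (chromosome 7, 35051544 to 35052283) opened on day 3 (0.55, adjusted p = 0.0188), with 0.42 in batch 1 (adjusted p = 0.6) and 0.55 in batch 2 (adjusted p = 0.0607). No peak of the other 3 passed there, and no analysed peak was annotated to Jun or Ddit3.

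The ATAC libraries came in 2 batches, per the authors' deposited covariates, with 3 libraries of each batch on days 0 and 3 and batch 2 alone on day 1. With a batch term, 36123 peaks changed between days 0 and 3 (24923 more and 11200 less open), with 44367 inside batch 2 and 7162 inside batch 1, in each case with more gains than losses. With the trend with peak strength removed beside the batch term, 37971 were called, 23025 more and 14946 less open. The count with day alone was 9078 or 9223 without day 0 replicate 1 or 2. The authors' deposited table lists 30821 changed peaks for day 3, of which 13698 were called here with day alone and 26609 with the batch term, all in the same direction.

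Between day 0 and day 1, no peak passed with day as the only term (0 by edgeR, 20796 with an unadjusted p under 0.05), while DESeq2 called 9417, 134 more and 9283 less open. With the batch term edgeR called 11884 peaks, 8249 more and 3635 less open, and inside batch 2 40817, 22069 more and 18748 less open. Of the losses with the batch term 74.8% were at promoters, and of the gains 12%. The change on day 1 followed peak strength, with weak peaks gaining and strong peaks losing (Pearson r across peaks, which are not independent, -0.497 with day alone, -0.398 with the batch term and -0.366 inside batch 2). With that trend removed, 2752 peaks were called with the batch term, 2124 more and 628 less open. The count of 11884 was 1095, 5697 and 3111 without day 0 replicates 1, 2 and 3 and 4313, 470 and 419 without day 1 replicates 1, 2 and 3. The share of reads in peaks was 0.157 to 0.186 on day 1, 0.322 to 0.496 on day 0 and 0.173 to 0.456 on day 3. The authors' deposited table lists 5773 changed peaks for day 1, of which 0 were called with day alone and 2671 with the batch term, in the same direction.

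**Figure D4:**
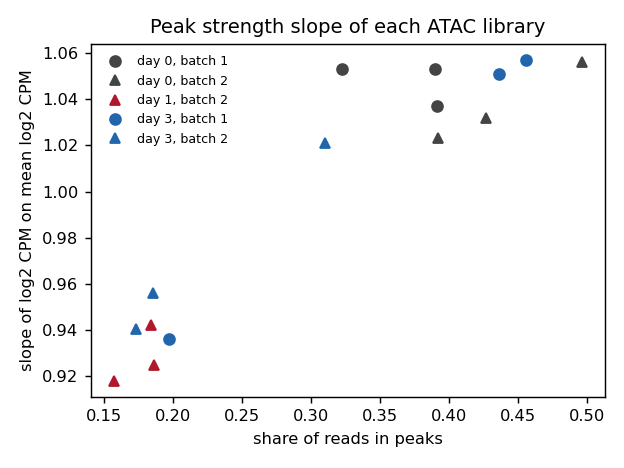
Slope of each ATAC library's log2 CPM on the mean log2 CPM of a peak, against the share of its reads that fall in peaks, for 15 libraries (colour, day; marker, batch). The day 1 libraries lie at shares of 0.157 to 0.186 and have low slopes, and libraries with higher shares have higher slopes.

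Between day 1 and day 3, edgeR again called 0 peaks with day alone (19696 with an unadjusted p under 0.05; DESeq2 2154), 1789 with the batch term (1496 more and 293 less open) and 15532 inside batch 2. The count of 1789 was 0 without day 1 replicate 1 or 2, 800 without day 3 replicate 1, 4452 without day 3 replicate 4 and 1072 without day 3 replicate 5.

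In the sorted cells, AP-1 motifs and those of several other factor families became more accessible by day 3, and other families less. The values are the authors' deposited chromVAR scores. Each is a deviation z-score of a library over all peaks with a motif, a relative measure and not an amount of accessibility. AP-1 motifs were higher in 29 of 30 cases on day 3 (median difference 69.5), with Jund motif 1 higher by 81.6 ± 7.03 (SE; limma adjusted p = 9.85e-07), Junb motif 3 by 81.2 and Fosl2 motif 1 by 78.2. Motifs of the CEBP and CHOP family were higher in 14 of 14 (10.9), of SOX factors in 14 of 14 (12.9), of CREB and ATF factors in 14 of 18 (7.12), of POU factors in 3 of 4 (5.90), and of LHX and NFI factors, fixed in advance as a family of glia, in 9 of 9 (24.2). Of 12 promoters of Mueller glia and astrocyte markers 4 were more open on day 3, and 8 with the batch term. Lower were the motifs of CTCF, the insulator protein (2 of 2; -45.5), of CRX and OTX factors of photoreceptors and bipolar cells (12 of 12; -39.4), of MEF2 factors (9 of 9; -15.7), KLF and SP factors (22 of 22; -8.39), EGR factors (8 of 10; -7.41), NRF1 (2 of 2; -10.8) and PU.1 of macrophages (5 of 8; -7.96). IRF and STAT motifs split, 4 higher and 16 lower of 20 (-9.98), with Stat3 motif 1 among the higher (10.3 ± 1.67). Of RFX motifs 2 were higher and 1 lower of 9, and of EBF motifs 1 of 3 was lower. With the batch term, 7 PU.1 and 2 EBF motifs were lower.

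In all, limma called 1063 motifs on day 3 (of 708 factors tested), 333 higher and 730 lower. The library median of all motifs differed between days, at 0.59 to 5.603 on day 0, -6.23 to -4.26 on day 1 and -2.01 to 0.35 on day 3. With each library centred on its median the split was 505 higher and 516 lower of 1021. Several family counts moved with it. RFX motifs were then higher in 7 cases and lower in 0, CREB and ATF motifs higher in 18 and POU motifs in 4, while KLF and SP motifs were lower in 19, EGR motifs in 5, PU.1 motifs in 2 (median -4.54), IRF and STAT motifs in 10 with 4 higher, and EBF motifs in 0. The counts of the AP-1, CEBP and CHOP, SOX, LHX and NFI, CTCF, CRX and OTX, MEF2 and NRF1 families were unchanged. Inside batch 2 there were 997 (306 higher, 691 lower) and inside batch 1 847 (279 of them higher).

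On day 1 most motifs stood lower as deposited, 980 of 1093 called with limma and 113 higher (batch 2, 989 lower and 129 higher), whereas after centring 469 were higher and 383 lower. CTCF (2 of 2; median difference -40.2), CRX and OTX (12 of 12; -31.9), PU.1 (8 of 8; -30.2), IRF and STAT (20 of 20; -29.9), KLF and SP (22 of 22; -17.6) and EGR (10 of 10; -15.9) motifs were lower, and stayed lower in 2, 12, 8, 16, 21 and 8 cases after centring. MEF2 (9 of 9; -9.58) and NRF1 (2 of 2; -7.40) motifs were lower as deposited and in 0 and 0 cases after centring. LHX and NFI motifs were higher in 7 of 9 cases (14.7) and AP-1 motifs in 22 of 30 with 1 lower (22.7), or 9 and 30 after centring. Of CREB and ATF motifs 7 were higher and 2 lower of 18 (18 higher after centring). CEBP and CHOP motifs were lower in 2 of 14 as deposited and higher in 14 after centring, SOX motifs lower in 3 of 14 and higher in 9 after centring, POU motifs lower in 1 of 4 and higher in 3, EBF motifs lower in 3 of 3 and higher in 1, and RFX motifs lower in 3 of 9 and higher in 7. The day 1 score of Jund motif 1 was higher by 27.3 ± 8.603 (limma adjusted p = 0.009), and without day 1 replicate 1 by 21.8 (adjusted p = 0.0549 for Jund motif 1 z-score day 1 against day 0). The motif comparison of day 3 with day 1 was not planned. Set against day 1, day 3 had 815 motifs higher and 73 lower with limma (380 and 338 after centring, 858 and 74 inside batch 2). Among those higher were AP-1 (28 of 30, median difference 46.7), CEBP and CHOP (14 of 14, 12.1) and IRF and STAT (20 of 20, 19.7), or 26, 12 and 20 after centring.

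**Figure D5:**
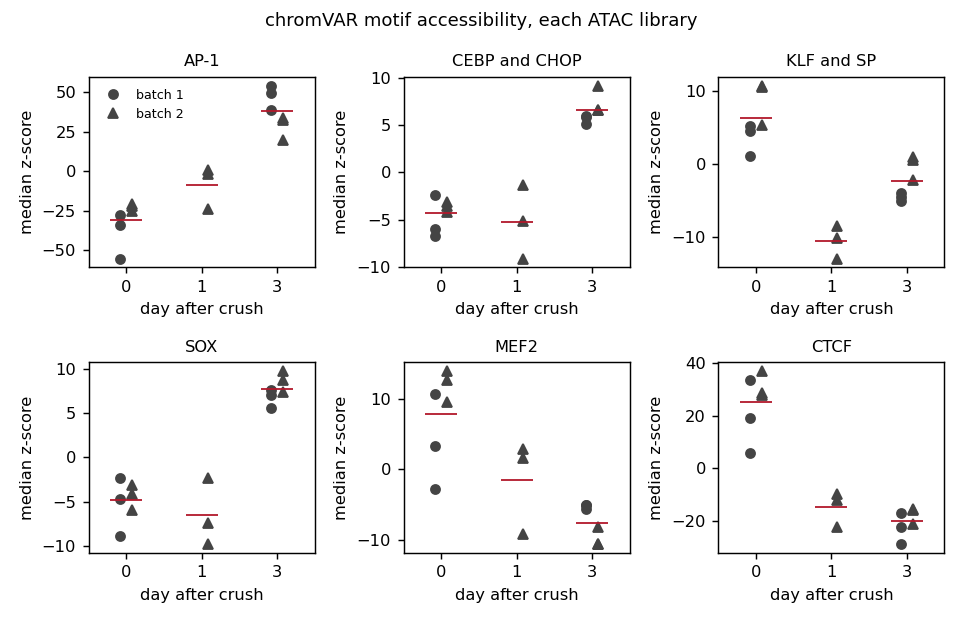
Median chromVAR score over the motifs of 6 families (AP-1, CEBP and CHOP, KLF and SP, SOX, MEF2 and CTCF) in each of the 15 ATAC libraries on days 0, 1 and 3 (circles, batch 1; triangles, batch 2; red line, day mean). AP-1 rises by a median of 69.5 to day 3, while CTCF falls by 45.5 without recovering from day 1.

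Promoter accessibility and RNA moved together only weakly. Across 11840 genes with a promoter peak on day 3, the log2 changes of both had a Pearson r of 0.0858 and a Spearman rho of 0.0717 (permutation p = 1e-05 each, the smallest that 100000 resamples give; 0.0801 with the batch term), where genes are not independent replicates. Inside batch 2 the r was 0.0854 and inside batch 1 0.0374 (permutation p = 8e-05). Of the called genes on day 3, 38 had more RNA and a more open promoter (odds ratio 1.86, 95% interval 1.22 to 2.78; Fisher's exact adjusted p = 0.00534) and 82 less RNA and a less open promoter (1.56, 1.19 to 2.03; adjusted p = 0.00444). With the batch term these were 141 (1.35, 1.10 to 1.65) and 579 (2.35, 2.10 to 2.64). More RNA with a less open promoter was found for 42 genes (240 with the batch term), and less RNA with a more open one for 8 (102). On day 1 the r of 0.211 (rho 0.153) with day alone did not hold with the batch term (r -0.00357, permutation p = 0.696) or inside batch 2 (0.00352, permutation p = 0.705). The rho was slightly negative there, at -0.0373 with the batch term (permutation p = 3e-05) and -0.0323 inside batch 2 (permutation p = 0.00041). Of photoreceptor promoters, 6 of 12 for rods and 5 of 7 for cones were less open on day 3, and 4 of 12 Mueller glia promoters were more open (10, 6 and 8 with the batch term). The lists of promoters were not tested as groups, and 1 of 39 promoters of excitability genes closed with day alone and 18 with the batch term. Of 6 promoters of vascular markers 1 was more open on day 3 with day alone, and with the batch term 4 were more and 1 less open. Whether the share of other cells in the ATAC samples differed between days was not tested. The accessibility changes therefore cannot be assigned to RGCs alone.

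The authors' deposited footprint tables list predicted binding sites of ATF3, ATF4, CEBPG and DDIT3 (CHOP) whose footprint score was higher on days 1 and 3 than on day 0, so that their bound shares rise partly by construction. Their columns, like those of the authors' comparison tables, carry the tag nonTarget or NT, which the labels do not explain, and they were read here as the uninjured and crushed samples by day. For ATF3 they hold 20364 sites, 33.9% at promoters, bound in 32.6%, 72.7% and 81.5% of cases on days 0, 1 and 3. For ATF4, CEBPG and DDIT3 they hold 6158, 9293 and 6365 sites, of which 77.4%, 78.4% and 77.8% were bound on day 3. Sites of ATF4, CEBPG and DDIT3 were largely shared. Of DDIT3 sites 67.3% lay within 4 bp of a CEBPG site and 56.2% within 4 bp of an ATF4 site, and 54.9% of CEBPG sites lay as near to an ATF4 site, against 6.53% of ATF4 sites near an ATF3 site, so that the values of these 3 factors below are not separate results. Genes with a promoter site bound on day 3 but not on day 0 had higher RNA on day 3 more often than other genes, for ATF3 in 26.4% against 20.3% of cases (odds ratio 1.41, 95% interval 1.22 to 1.62; Fisher's exact adjusted p = 1.51e-05), for ATF4 with an odds ratio of 1.39 (adjusted p = 0.007), for CEBPG 1.27 (adjusted p = 0.0189) and for DDIT3 1.38 (adjusted p = 0.00735). The same genes had higher RNA on day 1 more often as well, with odds ratios of 1.80 for ATF3 (adjusted p = 3.34e-06), 1.74 for ATF4 (0.00357), 1.75 for CEBPG (0.000325) and 1.87 for DDIT3 (0.000695). Lower RNA on day 3 was not more frequent for any of the 4 (odds ratios 0.943 to 1.07, none passing Fisher's exact test). Of 33 integrated stress response genes with a promoter peak, 14 had a promoter site of ATF4 bound on day 3, bound before or not, against 8.07% of other genes (odds ratio 8.39, 95% interval 3.88 to 17.7; Fisher's exact adjusted p = 4.01e-07), 15 a CEBPG site (6.21; adjusted p = 3.29e-06), 12 a DDIT3 site (7.01; adjusted p = 3.75e-06) and 9 an ATF3 site (1.22; adjusted p = 0.68). This list was set up as a program driven by ATF4, and whether a promoter holds the motif was not controlled for. These values therefore do not show binding gained after crush.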

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

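The tests of library batch, microglia RNA, nerve crush alone and a crushed sample labelled as uncrushed, and the splits of the RNA libraries and of the motif comparison of days 3 and 1, were chosen only after the result was seen. A difference between days stood out for 2 gene lists. The median log2 change of day 3 directly against day 1 was -3.46 over the interferon list and -2.20 over the microglia and macrophage list. Against day 0, the medians on days 1 and 3 were 1.24 and -1.93 for interferon and 1.78 and -0.75 for microglia and macrophages. In the direct comparison of day 3 with day 1, 24 of 28 interferon genes and 14 of 17 microglia genes were lower with edgeR, and 1 of each was higher. By camera both lists were lower (adjusted p = 9.68e-07 and 0.00496), which was lost at adjusted p = 0.426 and 0.698 with an estimated correlation. A single library far from the others was looked for in 42 groups of 6 ATAC libraries, of days 0 and 3 only, and 0 were found. RNA libraries and the day 1 ATAC libraries were not screened, since their groups are smaller. Each group of 6 pooled both batches, whose spread can hide a single library.

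On day 1, weak peaks gained and strong peaks lost accessibility. Batch is argued against, because the relation held inside batch 2 (r = -0.366 across peaks). The fitted curve of that trend does not account for every call, since 2752 peaks were still called with the trend removed and a batch term. A lower signal that acts other than through this curve was not tested. Libraries were not left out in turn for this count, while the 11884 calls before removal fell to 419 without day 1 replicate 3. A lower share of reads in peaks in the day 1 libraries stays open as a candidate explanation. With day and batch means taken out, the slope of a library on peak strength went with its share of reads in peaks over 15 libraries (Pearson r = 0.94, permutation p = 0.0123; Spearman rho = 0.839, permutation p = 0.0216; r = 0.857 without the 2 farthest libraries). Whether that share was lower through the injury or through handling was not tested.

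Interferon-induced genes were higher in day 0 replicate 3 than in the other 2 uninjured libraries. Microglia or macrophage RNA is argued against, because their summed markers stood at 0.684 of the mean of the other 2. The interferon sum was 2.02 times that of the lowest library of days 1 and 2, but this value is part of the pattern itself and decides nothing about nerve crush alone. A crushed sample labelled as uncrushed is argued against by a summed axon injury list at 0.428 of the lowest library after crush. Sequencing quality cannot be told apart from other causes, because the closest of 7 sequencing components followed the interferon sum with r = -0.553 over 13 libraries (permutation p = 0.0833, adjusted p = 0.291; Spearman rho = -0.473, permutation p = 0.135; r = -0.230 without the 2 farthest).

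The level of Xist differed between libraries of the same day by up to 530-fold on day 0 and, after crush, by up to 157-fold on day 3. The 157-fold is the pattern itself and decides nothing about nerve crush alone. The libraries held 206, 0.389 and 0.739 CPM on day 0, 1160 to 1830 on day 1, 0.561 and 1.3 on day 2, 962, 6.11 and 895 on day 3, and 4690 and 3580 on day 4. Libraries of days 1, 2 and 4 were alike within the day and differed between days, so that a difference in sex between the days compared stays open for every RNA comparison. More cells of female animals in some libraries may account for it. With day means taken out, the mean of 5 genes that escape X inactivation went with Xist over 13 libraries (Pearson r = 0.736, permutation p = 0.0151; Spearman rho = 0.786, permutation p = 0.0147; r = 0.574 without the 2 farthest).

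Other splits of the same libraries show how far a chance division of them can be excluded. For RNA there are 10 splits for 3 libraries against 3, too few for a share under 0.05, with 1563, 5564 and 4605 genes in the real splits (days 1 and 3 against day 0, and day 3 against day 1) and at most 0 in the others, so that 1 split of each 10 was as large. For ATAC with day alone, the real split of days 1 and 0 called 0 of 20000 peaks, so that 84 of 84 splits called as many by necessity and chance was not tested. The splits reached up to 4557 in a split whose group of 3 libraries was all batch 1. For days 3 and 1 this was likewise 0 peaks, 84 of 84 splits and up to 3692. The highest counts point to the batches as a structure of the libraries. For days 3 and 0 the real split called 1896 peaks and 3 of 100 splits called as many, the highest other being 4919 with 5 of 6 libraries of a group from batch 1. Inside batch 2, 40817, 44367 and 15532 of all peaks were called for days 1 and 3 against day 0 and day 3 against day 1. With a batch term and splits made within batches, the real count for days 3 and 0 was 4744 and the highest other 3794 (1 of 100 splits). A chance division of these libraries is argued against. Chance differences between animals are not covered, since the labels do not say that replicates came from separate animals. For days 1 and 0 and days 3 and 1 there are 10 splits within batches, too few, with real counts of 1624 and 335 and at most 0 in the others. For motifs, day 3 against day 0 had 1063 against at most 711 (1 of 100 splits), with splits drawn without regard to batch. The same limit on animals applies there. For day 1 against day 0 (1093 against 922; 1 of 84) and day 3 against day 1 (888 against 215; 1 of 84) the splits mix batches while day 1 is batch 2 alone, and the 10 splits within batches would be too few. Inside batch 2, 1118, 997 and 932 motifs were called for days 1 and 3 against day 0 and day 3 against day 1.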

How the results depend on the processing

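The settings with a batch term, single batches, a removed strength trend, deposited normalized or batch-adjusted values and sequencing components were chosen only after the result was seen. For the comparisons with 1 main value or count, 97 of the alternatives other than leaving out a library kept direction and side of the threshold (a count within 1.5 times), 18 gave more, 17 gave less and 3 reversed. For named genes, peaks, motifs and lists these were 3847, 81, 122 and 7. Where a value below moved, the cause was not tested, except that a minimum fold passes fewer by construction.

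The RNA count of day 1 was 815 with only the compared groups in the fit. At a fold change of at least 2, 366, 1294, 2136 and 2344 genes passed on days 1 to 4 and 1603 for day 3 against day 1. With sequencing components as terms, 1097, 2948, 5491 and 3895 passed. Of 46 camera calls, 23 were made with an estimated correlation. By fry there were 52. Calls of camera not made by fry were cholesterol synthesis (adjusted p = 0.0647) and rods (0.1) on day 1, interferon on day 2 (0.113) and microglia on days 1, 2 and 4 (0.154, 0.0897 and 0.0992). Made by fry and not by camera were, besides the signalling and receptor lists in the report, endoplasmic reticulum chaperones on days 3 and 4 (0.00188 and 0.00135), immediate early genes on day 3 (0.0013) and Mueller glia on days 1 and 4 (0.0276 and 0.0173).

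ATAC depended most on how batch entered. Replicates 1 to 3 were all of batch 2 and replicates 4 to 6 of batch 1, so replicate number as a term takes out batch as well. In the order of day 1 against day 0, day 3 against day 0 and day 3 against day 1, the counts were 0, 14466 and 0 with day alone, 11884, 36123 and 1789 with a batch term, 6212, 33565 and 1090 with replicate number as a term, 2312, 38531 and 11500 with limma on the deposited batch-adjusted values, and 40817, 44367 and 15532 inside batch 2. Inside batch 1, day 3 against day 0 gave 7162. DESeq2 gave 9417 for day 1 against day 0 and 2154 for day 3 against day 1, the share of reads in peaks as a term 6064 for day 3 against day 0, only the compared groups 7277 for day 1 against day 0, and a fold of at least 2 6898 for day 3 against day 0. Beside the batch term, the share of reads in peaks gave 895, 21294 and 7961, a fold of at least 2 3121, 9495 and 644, library size alone 27188 for day 1 against day 0 and 3951 for day 3 against day 1, and the removed trend 2752 for day 1 against day 0.

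Promoter accessibility against RNA on day 1 reversed from r = 0.211 to -0.00842 with replicate number (permutation p = 0.36), -0.00357 with a batch term (0.696) and -0.0869 with the trend removed as well (1e-05, the smallest that the permutations give), and was 0.00352 inside batch 2 (0.705). Each of these settings takes the batch difference out of the ATAC values, so they are not separate results. On day 1, centring turned Batf3 motif 1 (2.15), Cebpe motif 1 (4.65) and Ebf1 motif 2 (2.46) higher, with limma adjusted p = 0.0228, 0.000456 and 0.0484. Pou4f1 motif 1 (1.97), Sox2 motif 2 (2.96), Rfx5 motif 1 (0.329) and Nrf1 motif 2 (0.488) changed sign but did not pass. Their limma adjusted p was 0.230, 0.0801, 0.767 and 0.803.

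Leaving out each library in turn gave 1024 to 1563 genes on day 1, 2427 to 3958 on day 2, 4816 to 5329 on day 3, 4098 to 5261 on day 4, 3827 to 4134 for day 3 against day 1 and 5823 to 6508 on any day. On days 2 and 4 this leaves 1 library, assumed to vary like the other groups. ATAC counts with day alone were 0 to 0, 9078 to 20403 and 0 to 0, and with a batch term 419 to 16473, 28395 to 41011 and 0 to 4452. Motif counts were 947 to 1140, 1010 to 1085 and 769 to 889, and camera calls 45 to 49. Replicate numbers did not pair the RNA libraries (r of same-numbered pairs after removing day means -0.127 to 0.0663, of others -0.0846 to 0.0858).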

Other observations

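All values in this part were chosen only after the tables had been read, and no explanation was tested for them. The deposited table of correlations between the motif score and the RNA of the same factor holds 338 factors, of which 79 had a positive and 69 a negative value at the authors' p under 0.05. It gives 0.684 for Atf3, 0.767 for Atf4, 0.629 for Cebpg, 0.742 for Ddit3, 0.795 for Jun, 0.897 for Fosl2, -0.428 for Junb (the authors' p = 0.112), 0.594 for Mef2c, 0.659 for Sox11, -0.873 for Pou4f2, -0.684 for Ctcf and -0.108 for Pou4f1 (the authors' p = 0.702). These correlations run over days, so that measures that change with the day in step can have a large value for that reason alone.

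Peak calls of single ATAC libraries numbered 190918 to 380066 on day 0, 157899 to 227908 on day 1 and 143993 to 247748 on day 3. These ranges rest on matching each peak list to a library by its title and by the peak total in the authors' metadata, since the description of each sample names the list of another. Counting each interval once, these were 98555 to 144366, 70526 to 93147 and 68336 to 124298 intervals. They overlapped 51.5% to 74.0%, 34.3% to 44.3% and 35.8% to 64.8% of the analysed peaks.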
